A study of Mus musculus with 2 samples.

How the data were processed

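Long-read RNA sequencing libraries were made from total RNA of adrenal glands of male B6CASTF1/J mice 4 days after birth, per the labels. The series holds 2 libraries, biological replicates 1 and 2 of 1 group, with 1 technical replicate each. The animals behind them are not fully clear from the labels: the tissue descriptions name male 04 for replicate 2 and male 03 for replicate 1, while both library descriptions name male 03 and the donor identifier is the same. The libraries were treated as the biological replicates that the labels state. No group contrast exists, so levels within the tissue and differences between the 2 libraries were reported.

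The deposited quantification files give raw counts of long reads per transcript model, 1 file per library, without normalization, and list only models with at least 1 read. Per the file descriptions deposited with them, the counts rest on filtered alignments to the mouse genome build mm10 with the GENCODE mouse release 21 annotation of the primary assembly and ERCC spike-in sequences. Per the file headers, transcript models carry tags of the TALON program, which names each model as known, incomplete splice match, new combination of known splice sites, new splice site, genomic, antisense or intergenic. The aligner, tool versions and filters are not given in the sources used here. The deposited annotation files gave exon coordinates (mm10, counted from 1) and intron chains, and no measurement. Spike-ins were Ambion mix 1 and a Lexogen set with long SIRVs, per the labels; the SIRVs were not analysed here.

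Reads of a gene were summed over its transcript models. CPM used all reads assigned to mouse genes, known or new, with spike-ins left out, 688436 for replicate 1 and 810818 for replicate 2. A gene or list with 0 reads may hold up to 3 reads, which equal 4.36 and 3.70 CPM. Such floors and all confidence intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Shares of reads were given with 95% Wilson intervals and ratios of few reads with exact Clopper-Pearson intervals of the counts. Coordinates of genes come from the GENCODE mouse release 21 annotation.

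The following choices were made before the data were examined: the tests, their thresholds, the gene lists and the rule for naming genes. Genes were compared between the libraries with a two-sided Fisher's exact test of the reads of the gene against all other mouse reads, with Benjamini-Hochberg adjustment over the 8276 genes with at least 20 reads over both libraries. A gene was called at an adjusted p under 0.05 and a log2 ratio of CPM of at least 1 in size, with 0.5 CPM added to each value. With 1 library on each side, this compares the libraries and not the animals. For each gene list with at least 3 tested members, the median log2 ratio was set against 10000 random lists of the same size, matched in 10 strata of mean expression. Agreement was measured with Pearson's r and Spearman's rho of log2 levels across genes. Shares of reads by transcript class were compared with a chi-square and Cramér's V.

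Isoform shares used complete-match and new-splice models, with incomplete and genomic ones left out, for 2440 genes with at least 50 such reads in each library. Known models were matched between libraries by transcript identifier and new ones by exact intron chain on the same strand. Usage of the leading model was compared with a two-sided Fisher's exact test, Benjamini-Hochberg adjustment and a minimum difference of 10 points. Introns of new loci were compared with annotated introns of the opposite strand, a comparison chosen after the values were seen.

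The 20 gene lists were steroid synthesis, zona glomerulosa, zona fasciculata and X-zone, cholesterol synthesis, chromaffin, Schwann and sustentacular glia, capsule and stroma, endothelium, macrophage, red blood cell, fat, kidney, liver and pancreas, muscle, gonadal steroid, cell cycle, imprinted growth, immediate early and stress, mitochondrial genome, and Y-linked genes. Genes named were the 20 with the highest mean CPM and the 4 most abundant of each list, or any member of the steroid, chromaffin, imprinted and Y-linked lists. Also named were the 10 called genes with the largest log2 ratio in each direction, the leading isoforms of the steroid, chromaffin and imprinted lists, and the 10 other abundant genes whose leading known model held under 60% of reads. The rule further took the 10 genes with the largest called difference in isoform usage, the 15 most abundant new isoforms and the 5 most abundant new loci found in both libraries. List members outside this rule were named where a count of 5 or fewer or the called members of a list called for it, after their values were seen. A list of 30 hepatocyte genes was added after the data were seen.

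Alternatives were TMM scaling (edgeR) and DESeq2's size factors, other read minimums, other pseudocounts, and counts without genomic models or from known models alone. Other thresholds for isoforms and each library left out were also run. The tests were run on simulated data with known answers for the comparison of library 2 with library 1. Of 200 genes changed 2-fold among 8288 tested, 52% were called and 90.5% passed on the p alone, with 2 false calls. Of 200 changed 4-fold among 8285 tested, 100% were called, with 4 false calls, and of 200 changed 1.5-fold among 8261 tested, 4% were called and 37% passed on the p alone. The changed genes were drawn from those with at least 100 reads, which 3144 tested genes have, so recovery of genes with fewer reads was not measured. Simulated reads varied by counting error alone, less than the genes of these libraries did, so the false calls do not carry over to them. Of 200 lists without a shift, 5.5% fell outside the central 95% of random lists, and 99% of 200 lists shifted by 0.5 did. For isoform usage, a difference of 20 points was simulated in 200 of 1000 genes. Of these 88.5% were called, with 4 false calls among the genes without a difference. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used. Alleles of the 2 parent strains were not analysed here, since the files hold no sequence.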

Results

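Long-read RNA sequencing measured the transcripts of the adrenal gland in male mice 4 days after birth. The mice were of the strain B6CASTF1/J, the offspring of a cross between C57BL/6J and CAST/EiJ mice. There was 1 group of 2 biological replicates, with 1 library each, and no treatment or other condition. Replicate 1 held 707726 reads, of which 688436 were assigned to mouse genes, and replicate 2 held 832552 reads, of which 810818 were assigned to mouse genes. Levels are in CPM, the reads of a gene scaled to a common total of mouse reads. A single read equalled 1.45 CPM in replicate 1 and 1.23 CPM in replicate 2. Known genes with at least 1 read numbered 15535 in replicate 1 and 16618 in replicate 2, of which 14100 were shared, out of 18053 found in either library. Protein-coding genes took 93.2% and 91.3% of the mouse reads. The 20 most abundant genes of each library, ranked in that library alone, took 9.44% and 9.08% of them. Values are mean ± SD over the 2 libraries (n = 2), and ratios are replicate 2 over replicate 1 on the log2 scale.

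The levels address which hormone-making pathways the gland expressed a few days after birth. Genes of corticosteroid synthesis led the ranking of single genes and had the largest sum of the fixed lists. Cyp21a1 (ENSMUSG00000024365.9, steroid 21-hydroxylase, chromosome 17, 34801348 to 34804561, mm10) had the highest mean of all genes at 13978 ± 6055 CPM. Cyp11a1, which cleaves the side chain of cholesterol (ENSMUSG00000032323.13, chromosome 9, 58006411 to 58027023), followed at 11530 ± 190 CPM. In replicate 2 Cyp11a1 exceeded Cyp21a1, with 11396 against 9696 CPM. Without genomic models, Cyp11a1 had 6626 CPM, so its level rests in part on single-exon fragments. Hsd3b1, the 3-beta-hydroxysteroid dehydrogenase of the gland (ENSMUSG00000027871.16, chromosome 3, 98852194 to 98859794), had 6553 ± 2300 CPM. Cyp11b1, which makes corticosterone (ENSMUSG00000075604.5, chromosome 15, 74834125 to 74841643), had 4391 ± 1384 CPM, and the aldosterone synthase gene Cyp11b2 had 533 ± 304 CPM. Star, which brings cholesterol into mitochondria, had 1486 ± 232 CPM. The electron carriers Fdx1 and Fdxr had 765 ± 94.9 and 666 ± 180 CPM, and the P450 reductase gene Por had 198 ± 34.2 CPM. The cortex transcription factor genes Nr5a1 and Nr0b1 had 572 ± 141 and 108 ± 26.6 CPM. The lipoprotein receptor gene Scarb1 had 440 ± 96.1 CPM, the cholesterol esterification gene Soat1 had 158 ± 40.9 CPM and the zona glomerulosa gene Hsd3b6 had 63.7 ± 29.0 CPM. Summed over the 16 genes of steroid synthesis, all found in both libraries, the level was 41851 ± 11174 CPM, or 4.98% and 3.39% of the mouse reads of replicates 1 and 2.

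The corticotropin receptor gene Mc2r (chromosome 18, 68406907 to 68429320, minus strand) had 55.4 ± 12.1 CPM, and its accessory protein gene Mrap had 353 ± 55.8 CPM. Reads with both introns of Mc2r on the opposite strand were more numerous than the reads counted for the gene. They numbered 158 and 196, against 44 and 38 reads on the gene's own strand. With them, Mc2r would hold 293 and 289 CPM instead of 63.9 and 46.9. The strand of those reads was examined after their values were seen, and the count of Mc2r is a lower limit if they are Mc2r reads.

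Genes of the cortical zones were present beside the shared enzymes. The zona glomerulosa list summed to 3252 ± 985 CPM over 10 genes, led by the potassium channel gene Kcnk3 at 1999 ± 519 CPM, Cyp11b2, the signalling gene Wnt4 at 362 ± 89.9 CPM and Dab2 at 155 ± 13.2 CPM. The list of zona fasciculata and X-zone genes summed to 5948 ± 2240 CPM over 5 genes. Beside Cyp11b1 it held Akr1c18, the progesterone-degrading enzyme gene of the X-zone, at 1322 ± 854 CPM and Akr1b7 at 175 ± 11.8 CPM. Cholesterol synthesis genes were far less abundant, with 1047 ± 144 CPM over 20 genes. Dhcr7 led them at 243 ± 103 CPM, followed by Hmgcs1 at 196 ± 29.2 CPM, the sterol sensor gene Insig1 at 82.2 ± 19.7 CPM and Fdps at 77.3 ± 0.504 CPM.

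Of the fixed lists, that of the adrenal medulla had the next largest sum. Genes of chromaffin cells summed to 13668 ± 2514 CPM over 18 genes. The granule protein genes Chga (chromosome 12, 102554969 to 102565028) and Chgb stood at 4117 ± 991 and 3379 ± 628 CPM. Th, the tyrosine hydroxylase gene that starts catecholamine synthesis (chromosome 7, 142892752 to 142931128), had 2025 ± 523 CPM, and Pnmt, which turns noradrenaline into adrenaline, had 989 ± 57.6 CPM. The granule gene Scg2 had 1089 ± 138 CPM, the neuropeptide gene Npy 810 ± 39.7 CPM, the electron carrier gene Cyb561 492 ± 81.3 CPM and the dopamine hydroxylase gene Dbh 349 ± 68.6 CPM. The transcription factor genes Phox2a and Gata3 were measured at 35.4 ± 1.26 and 39.6 ± 15.9 CPM, and Hand2 at 34.9 and 41.9 CPM in replicates 1 and 2. The opioid peptide gene Penk had 67.0 ± 6.42 CPM, Scg5 had 105 ± 12.4 CPM, and the decarboxylase gene Ddc had 28.9 ± 7.98 CPM. The vesicular monoamine transporter genes Slc18a2 and Slc18a1 had 28.8 ± 9.88 and 24.0 ± 11.3 CPM.

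Of the 20 most abundant genes, 7 were Cyp21a1, Cyp11a1, Hsd3b1, Cyp11b1, Chga, Chgb and Th, and the others served wider functions. The lipid carrier gene Apoe had 5701 ± 4628 CPM, a mean that rested on replicate 2 (2429 and 8974 CPM) and was 3565 CPM without genomic models. There were the alcohol dehydrogenase gene Adh1 at 4285 ± 526 CPM, the ubiquitin gene Ubb at 4072 ± 71.1 CPM and the aldo-keto reductase gene Akr1cl at 2863 ± 878 CPM. The cell cycle inhibitor gene Cdkn1c (chromosome 7, 143458339 to 143461050), which is imprinted, had 3921 ± 530 CPM. The transferrin gene Trf had 3017 ± 3946 CPM, a mean that rested on replicate 2 (227 and 5806 CPM). The globin gene Hba-a1 had 2945 ± 1336 CPM. The ATP synthase gene Atp5b had 3029 ± 13.4 CPM, Cox4i1 2774 ± 293 CPM, the matrix gene Sparc 2706 ± 378 CPM, the imprinted signalling gene Gnas 2212 ± 86.5 CPM and the iron storage gene Fth1 2058 ± 98.2 CPM.

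Other cell types of the gland were represented at lower levels. The capsule and stroma list summed to 5341 ± 484 CPM over 12 genes, with the collagen genes Col3a1 at 1359 ± 447 CPM, Col1a1 at 590.5 ± 297 CPM and Dcn at 231 ± 29.0 CPM behind Sparc. Endothelial genes summed to 888 ± 29.9 CPM over 10 genes, led by the fenestral diaphragm gene Plvap at 427 ± 41.7 CPM and Egfl7 at 196 ± 19.9 CPM. Macrophage genes summed to 386 ± 10.6 CPM over 10 genes, led by the complement genes C1qa, C1qc and C1qb at 101 ± 7.83, 82.6 ± 10.5 and 64.9 ± 2.77 CPM. Schwann and sustentacular glia genes summed to 86.0 ± 47.6 CPM over 8 genes, with Fabp7 at 20.8 ± 8.91 CPM and Mbp at 19.5 ± 9.07 CPM. Cell cycle genes summed to 2834 ± 10.5 CPM over 20 genes, of which the tubulin gene Tuba1b made up 1332 ± 84.9 CPM and the replication gene Mcm2 180 ± 6.61 CPM. Immediate early and heat shock genes summed to 2486 ± 893 CPM over 15 genes, of which the chaperone gene Hspa8 made up 1696 ± 582 CPM. Genes of the mitochondrial genome summed to 738 ± 275 CPM over 15 genes, with the cytochrome oxidase gene mt-Co1 at 362 ± 142 CPM.

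Imprinted genes of early growth summed to 9066 ± 518 CPM over 19 genes. After Cdkn1c and Gnas came the adipogenesis inhibitor gene Dlk1 at 919 ± 92.9 CPM, the neuronal growth suppressor gene Ndn at 509 ± 91.8 CPM and the noncoding RNA genes H19 and Meg3 at 376 ± 199 and 343 ± 99.1 CPM. Nnat had 303 ± 0.893 CPM, Mest 266 ± 38.3 CPM and Snrpn 90.9 ± 25.6 CPM. The fetal growth factor gene Igf2 had 66.6 ± 24.4 CPM. The Y-linked translation factor gene Eif2s3y had 58 and 63 reads (81.0 ± 4.63 CPM), and the helicase gene Ddx3y had 19 and 18. Uty had 5 and 4 reads and Kdm5d had 0 and 1. Xist, the RNA of the inactive X chromosome, had 0 reads in both libraries, which allows up to 4.36 and 3.70 CPM, and the list summed to 113 ± 9.22 CPM.

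Genes of neighbouring tissues were measured to see what else the libraries held. Brown and white fat genes summed to 2148 ± 395 CPM over 8 genes, led by the fatty acid carrier gene Fabp4 at 1092 ± 212 CPM, the heat-producing uncoupling gene Ucp1 at 313 ± 116 CPM and Cidea at 293 ± 61.4 CPM. From known models alone, without the incomplete matches that make up 84.3% and 81.4% of Fabp4 reads, the fat list had 1329.6 CPM. Striated muscle genes summed to 1906 ± 732 CPM over 6 genes, with the actin gene Acta1 at 1126 ± 378 CPM and Ckm at 404 ± 134 CPM. Kidney genes summed to 25.7 ± 17.1 CPM over 10 genes. In replicate 1 the reads came mostly from the phosphate transporter gene Slc34a1 (13 and 2 reads) and the water channel gene Aqp2 (12 and 2 reads). Most of the 11 reads of replicate 2 came from other members. The gonadal steroid genes gave 0 and 4.93 CPM over 6 genes, from 2 reads each of Cyp17a1 and Insl3 in replicate 2. Liver and pancreas genes summed to 270.2 CPM in replicate 1 and 9869 CPM in replicate 2 (5070 ± 6787 CPM over 10 genes).

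**Figure D1:**
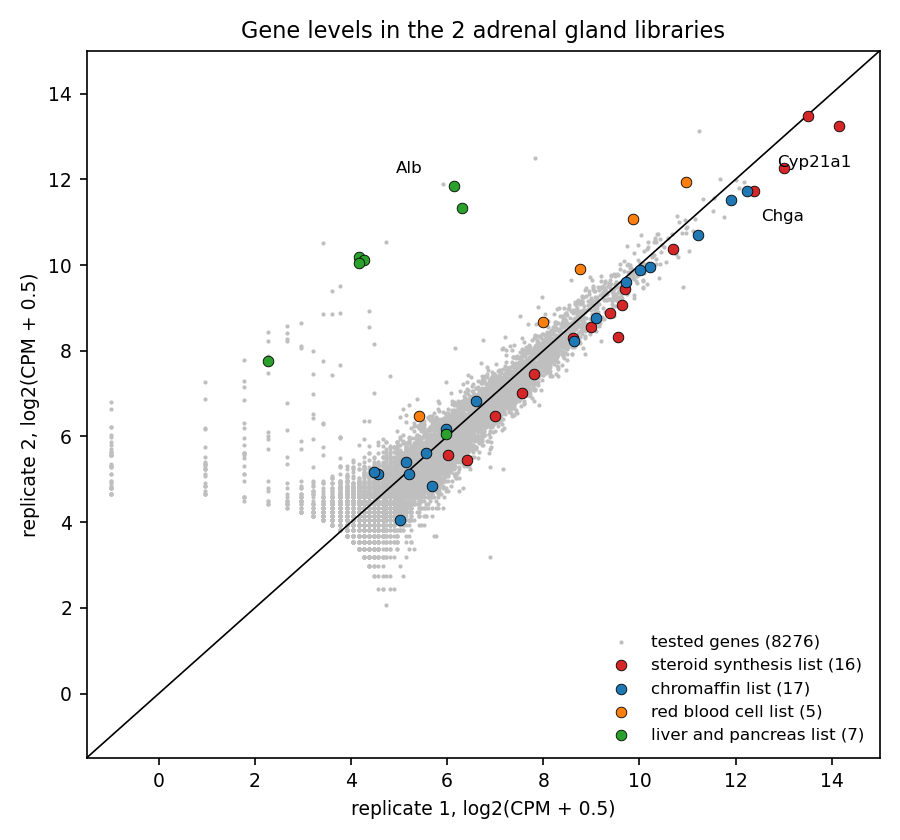
Level of each of 8276 tested genes in replicate 1 (x axis) and replicate 2 (y axis), as log2 of CPM plus 0.5, with the line of equality. Grey points are all tested genes; steroid synthesis (red), chromaffin (blue), red blood cell (orange) and liver or pancreas genes (green) are marked. The liver genes lie above the line, with a median log2 ratio of 5.71.

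The second question was which genes differed between the 2 libraries. Among the largest differences were genes known for their expression in liver. Kng1, the kininogen gene, had 10.2 CPM in replicate 1 and 1453 CPM in replicate 2, a log2 ratio of 7.09 with a counting standard error of 0.55. Reads of the lipoprotein gene Apom were counted only in replicate 2 (81 reads, at least 22.9-fold higher). The same held for the drug-metabolising gene Cyp3a11 and the clotting factor gene F12 (60 reads each, at least 16.98-fold), the plasminogen gene Plg (53 reads), Cyp2e1 (51 reads, at least 14.4-fold), Cfi (47 reads, at least 13.3-fold) and Afm (45 reads, at least 12.7-fold). Each of these bounds sets the reads of replicate 2 against 3 reads in replicate 1. Among the most abundant genes, Trf differed by 4.68 and Apoe by 1.89. In all, 92 tested genes had a log2 ratio of at least 4 with 0.5 CPM added, some of them with 0 reads in replicate 1, where the ratio depends on that addition. They took 3.35% of the mouse reads of replicate 2, against 771 CPM in replicate 1. The most negative log2 ratio was −3.69, so 0 tested genes lay at −4 or lower.

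The 10 largest differences in the other direction were smaller and rested on few reads. The pseudogene Oaz1-ps had 81 and 7 reads (log2 ratio −3.69, exact adjusted p 5.98e-18). It lies within AC154200.1 (chromosome 17, 17340820 to 17374206), which had 0 and 90 reads and is at least 25.5-fold higher in replicate 2. The pair together had 81 and 97 reads, so the count of each depends on where reads of the overlap were assigned, and both values are uncertain. The patterning gene Hoxc6 had 18 and 3 reads, a ratio of 0.142 with a counting interval of 0.0267 to 0.485. Cyb5d2 (20 and 4 reads), Scarf1 (19 and 4), Stk40 (23 and 5), Adal (17 and 4), the angiotensin receptor gene Agtr1b (17 and 4), Mtfmt (16 and 4), Metrnl (37 and 10) and Swt1 (19 and 5) lay between −2.44 and −2.08. Mtfmt did not pass the test with TMM or DESeq2 size factors.

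In total, 267 of 8276 tested genes passed the two-sided Fisher's exact test with an adjusted p under 0.05 and a log2 ratio of at least 1 in size. Of these, 187 were higher and 80 lower in replicate 2, so 70.0% were higher. With TMM scaling 258 passed, 211 higher and 47 lower (81.8% higher), and 234 of them were among the 267. DESeq2's size factors gave 256, 211 higher and 45 lower (82.4% higher), of which 232 were shared. The median log2 ratio of all tested genes was −0.10, and TMM and DESeq2's size factors moved it up by 0.10 and 0.11. Without the size threshold, 656 genes passed, 317 higher and 339 lower. Only 1 library stood on each side, so these differences have no replicate check: the test compares these libraries with counting error alone, not the animals.

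Steroid synthesis genes lay below the other genes in replicate 2. Cyp21a1 had 18259 and 9696 CPM (log2 ratio −0.91, counting standard error 0.021), Hsd3b1 8179 and 4927 CPM (−0.73) and Cyp11b1 5370 and 3413 CPM (−0.65). Cyp11b2 had 748 and 318 CPM and passed the test (−1.23, exact adjusted p 9.78e-29). Cyp11a1 had 11664 and 11396 CPM (−0.03, exact adjusted p 0.431), a ratio that was 0.07 with TMM scaling and −0.28 without genomic models. The median log2 ratio of the 16 genes was −0.51, below all of 10000 random lists of like expression (percentile 0, central 95% of random medians −0.27 to 0.14), and 15 of 16 lay under the median of all genes. Over all genes tested 1 member was called, and 1 adjusted over the list alone; 10 passed on the p alone, all lower. Hsd3b1 passed the size threshold when single-exon genomic models were left out (−1.004), a setting in which the 2 libraries name the same fragments differently.

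The outer and inner cortical lists, which share Cyp11b2, Hsd3b6, Cyp11b1 and Mc2r with the steroid list, went the same way. The zona glomerulosa list had a median of −0.51 over 9 tested genes (percentile 0.2), with Cyp11b2 and Agtr1b called over all genes, and 2 genes adjusted over the list alone. The fasciculata and X-zone list had a median of −0.55 over 4 tested genes (percentile 0.79). In it Akr1c18 was lower, with 1926 and 718 CPM (−1.42, exact adjusted p 2.75e-93), while Akr1b7 had a ratio of 0.14; 1 gene was called, and 1 adjusted over the list alone. With known transcript models alone the list stood at percentile 3.23. Mc2r entered this list and the steroid list with the 44 and 38 reads of its own strand. With the reads of the opposite strand it would hold 293 and 289 CPM, so the median of the fasciculata list depends on that count. Neither list was computed with those reads. Cholesterol synthesis genes had a median of −0.11 over 16 tested genes, at percentile 49.8. None passed over all genes, 0 adjusted over the list alone, and Dhcr7 (−0.89) passed on the p alone.

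The median of chromaffin genes lay close to that of all genes, while their summed level was lower in replicate 2 (15445 and 11890.5 CPM, ratio 0.770, against 0.682 for steroid synthesis). Their median was −0.12 over 17 tested genes, at percentile 39.5, against −0.10 for all genes. Th had a log2 ratio of −0.53, Chga −0.50, Chgb −0.38 and Scg2 −0.26, while Pnmt had −0.12 and Npy −0.10. None was called over all genes, 0 adjusted over the list alone, and 6 passed on the p alone, all lower: Th, Chga, Chgb, Scg2, Dbh and Cyb561.

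Liver genes set the other extreme. The liver and pancreas list had a median of 5.71 over 7 tested genes, at percentile 100, and 6 were called over all genes, and 6 adjusted over the list alone. The albumin gene Alb had 48 and 2984 reads, the fetal albumin-like gene Afp 12 and 943, the retinol carrier gene Ttr 13 and 905, and the lipoprotein genes Apoa1 and Apoa2 54 and 2077 and 12 and 862. The protease inhibitor gene Serpina1a had 3 and 175 reads, a ratio of 49.5 with a counting interval of 16.7 to 242. The pancreatic elastase gene Cela1 had 43 and 54 reads (0.09), the carboxypeptidase gene Cpa1 had 1 and 2, and Prss2 and Pnlip had 0.

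The medians of red blood cell, muscle, fat and stromal genes lay above those of random lists. Red blood cell genes summed to 3672 and 7489 CPM (5580 ± 2699 over 7 genes; the list's eighth, Ahsp, is not in the annotation under that name), with a median of 1.07 over 5 tested genes at percentile 99.99. The globin gene Hbb-bs (1.19), Hba-a2 (1.13) and the heme synthesis gene Alas2 (1.07) were called, and 3 genes adjusted over the list alone. Hba-a1 and Hba-a2 are near-identical copies, so the split of reads between them is uncertain. Muscle genes had a median of 0.87 over 5 tested genes (percentile 99.9), with the myosin light chain gene Mylpf called (1.28), and 2 genes adjusted over the list alone. Fat genes had a median of 0.41 over 7 tested genes (percentile 99.6), 0 called, and 1 adjusted over the list alone. Ucp1 (0.77), Cidea (0.43) and Fabp4 (0.40) passed on the p alone. In the capsule and stroma list Col1a1 was higher (381 and 800 CPM, 1.07), while Sparc had −0.29; its median was 0.32 over 9 tested genes (percentile 99.4), 1 gene called, and 1 adjusted over the list alone. With known models alone the median of the capsule and stroma list was 0.30, at percentile 97.4, inside the central 95%.

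The median of mitochondrial genes lay above random lists and that of immediate early genes below them. Genes of the mitochondrial genome had a median of 0.86 over 10 tested genes (percentile 100), mt-Cytb called (1.01), and 2 genes adjusted over the list alone. Immediate early and heat shock genes had a median of −0.71 over 11 tested genes (percentile 0), and all 11 lay under the median of all genes. The transcription factor gene Junb was called (241 and 106 CPM, −1.18), and 1 gene adjusted over the list alone; 5 passed on the p alone, among them Hspa8 (−0.71) and the transcriptional regulator gene Ier2 (−0.63).

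Glia genes had a median of 0.96 over 3 tested genes (percentile 97.6), and the other remaining lists lay within their random lists. Of the glia genes 1 was called over all genes, and 1 adjusted over the list alone. Endothelial genes had a median of 0.00 over 7 tested genes (percentile 70.0). Pecam1, an adhesion gene, was lower (37 and 16 reads, −1.42), and 2 genes adjusted over the list alone, the other being the growth factor receptor gene Kdr (4 and 19 reads). Macrophage genes had −0.15 over 7 tested genes (percentile 42.9), 0 called and 0 adjusted over the list alone. Cell cycle genes had −0.07 over 17 tested genes (percentile 71.5), 0 called and 0 adjusted over the list alone, with Ccnb2 (0.77) and Hmgb2 (0.66) passing on the p alone. Imprinted genes had −0.08 over 11 tested genes (percentile 47.2). H19 was called (235 and 517 CPM, 1.13), and 1 gene adjusted over the list alone, while Cdkn1c had −0.28 and Gnas −0.08. The medians of the endothelial, cell cycle and imprinted lists were above 0 with TMM scaling. Igf2 and Nnat passed the test with genomic models left out, where the 2 libraries name the same fragments differently. Too few kidney, gonadal and Y-linked genes were tested for a median.

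**Figure D2:**
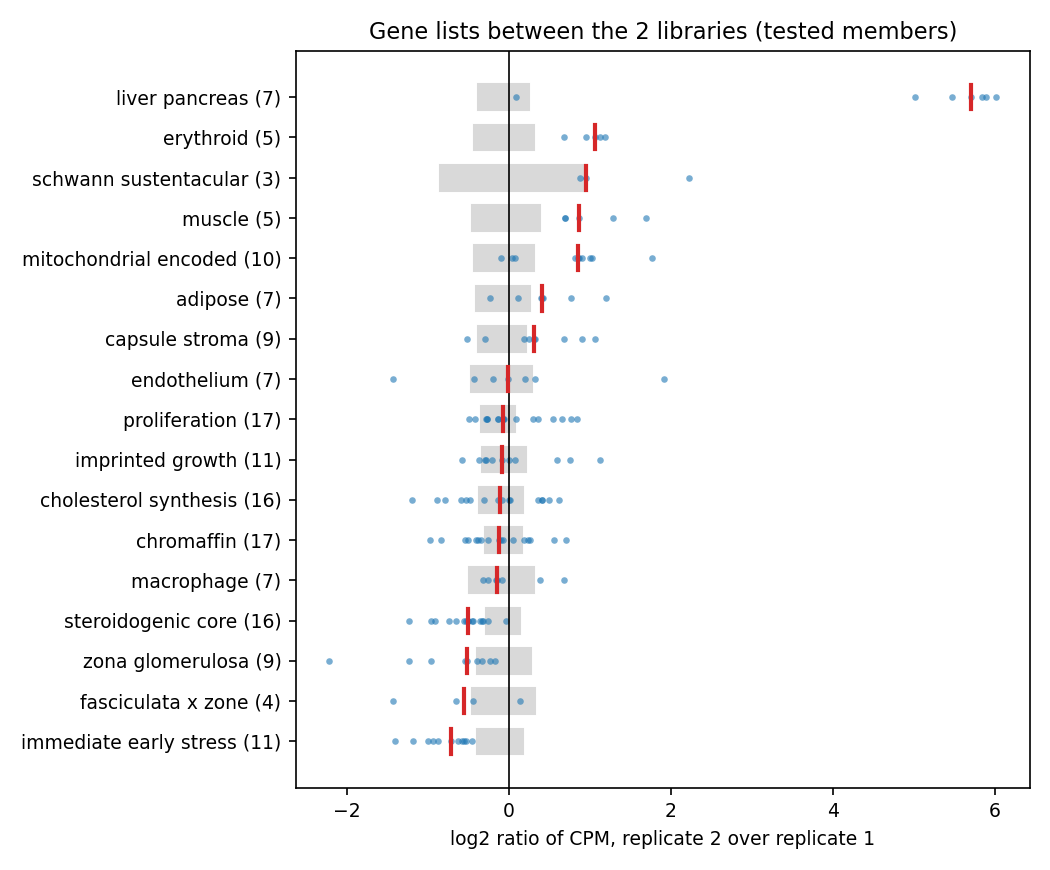
Log2 ratio of replicate 2 over replicate 1 (x axis) for the tested members of each gene list (blue points, number in parentheses), with the median of the list (red bar) and the central 95% of the medians of 10000 random lists of like expression (grey box). The steroid synthesis median of −0.51 lies left of its box, and the liver and pancreas median of 5.71 lies right of its box.

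Agreement between the libraries was measured across genes, which are not independent replicates. Pearson's r of log2 levels was 0.858 and Spearman's rho 0.893 over the 8276 tested genes. The r was 0.938 without genes with a log2 ratio of 3 or more. Spike-in RNAs took 2.73% and 2.61% of all reads, 19290 and 21734 reads. Of 96 spike-ins, 53 had a read in either library and 46 in both. The log2 ratios of the 11 spike-ins with at least 100 reads in each library had an SD of 0.141, where counting error alone gives 0.0963. The 1383 genes with at least 100 reads in each had an SD of 0.343, where counting error gives 0.149.

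Most reads matched annotated transcripts, the third subject measured. Complete matches took 74.2% (95% Wilson interval 74.1 to 74.3) of the mouse reads in replicate 1 and 70.1% (70.0 to 70.2) in replicate 2, or 72.1 ± 2.90%. Incomplete splice matches took 10.02 ± 0.673%, of which 67.0% and 68.0% kept the 3′ side of an annotated transcript alone. New combinations of known splice sites took 4.68 ± 0.0080% and models with new splice sites took 3.34 ± 0.153%. Genomic models, which match no annotated splicing, took 4.49% (4.44 to 4.54) and 6.35% (6.30 to 6.40). Reads antisense to known genes took 2.96% (2.92 to 3.00) and 4.25% (4.21 to 4.29), and intergenic reads 0.699% (0.680 to 0.719) and 0.913% (0.892 to 0.933). Reads by class differed between the libraries with a chi-square of 5495 on 6 degrees of freedom and a Cramér's V of 0.061. The names are not fully comparable: of 247 genes with at least 20 single-exon fragments in each library, 49 had over 80% of them named genomic in 1 library and under 20% in the other.

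**Figure D3:**
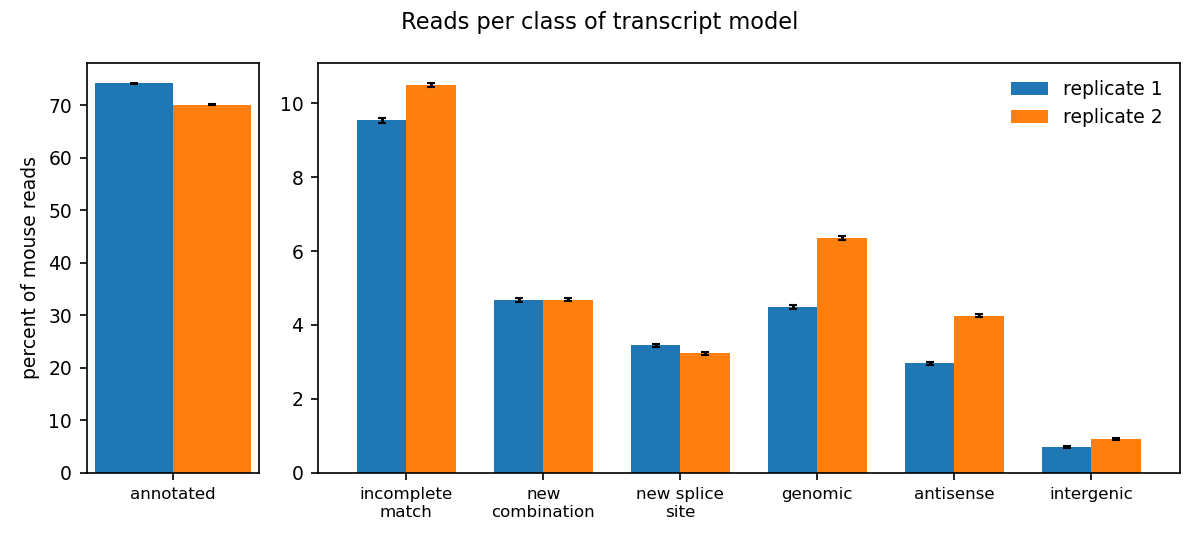
Percent of mouse reads in each transcript class (bars; replicates 1 and 2 side by side) with 95% Wilson intervals, the annotated class in a panel with its own axis. Complete matches hold 74.2% and 70.1%, and genomic models 4.49% and 6.35%.

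Isoforms were described for the main hormone genes. Star-201 took 97.6% and 96.3% of the complete and new-splice reads of Star, Cyp11b1-201 96.1% and 94.2%, and Cyp11a1-201 94.5% and 92.4%. Cyp21a1-201 took 91.6% (95% Wilson interval 91.0 to 92.1) in replicate 1 and 84.2% (83.4 to 85.1) in replicate 2, a difference of −7.32 points that passed the two-sided exact test on its p alone (exact adjusted p 2.58e-48) but not the 10-point minimum. Cyp11b2-201 had 89.4% and 81.8%, Fdx1-201 96.2% and 98.1%, Fdxr-201 83.3% and 82.7%, Scarb1-201 88.6% and 82.5%, Mrap-201 95.8% and 90.5%, Por-201 92.9% and 89.0%, Soat1-207 86.7% and 87.4%, Nr5a1-201 74.7% and 69.6%, and Nr0b1-201 100% in both. In the medulla, Chga-201, Chgb-201, Th-201, Pnmt-201, Npy-201, Dbh-201 and Scg5-201 each took at least 91.0% in both libraries. Scg2 was split between Scg2-202 (53.1% and 47.8%) and Scg2-201. Among imprinted genes, the leading shares were 94.1% and 95.2% for H19-202, 94.2% and 94.8% for Mest-211, 74.2% and 76.4% for Dlk1-205, 74.0% and 69.9% for Nnat-202, 79.2% and 86.4% for Snrpn-201, 67.5% and 68.6% for Gnas-208, and 100% for Ndn-201. Meg3-205 held 16.98% and 19.7% of the complete and new-splice reads of Meg3, whose leading model differed between the libraries.

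Models named incomplete or genomic changed what could be said of the most abundant genes. Most Hsd3b1 reads lay in a 4-exon model that starts at 98858341, within the gene, and lacks the annotated exon 1 (98859672 to 98859794). It held 4363 and 2789 reads, 77.5% and 69.8% of the gene's reads, and keeps the annotated start codon at 98857962 to 98857964. Its first exon begins where exon 2 of Hsd3b1-202 (98858152 to 98858341) begins. Whether this model is a fragment or a complete transcript was not tested. A 3-exon model that keeps an intron held 452 and 361 reads (8.03% and 9.04%). Both are named incomplete matches, so only 62 and 63 reads of Hsd3b1 entered the isoform shares. Of all Cyp11a1 reads, single-exon genomic models held 3245 and 4704 (40.4% and 50.9%), and Cyp11a1-201 held 48.5% and 38.5%.

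**Figure D4:**
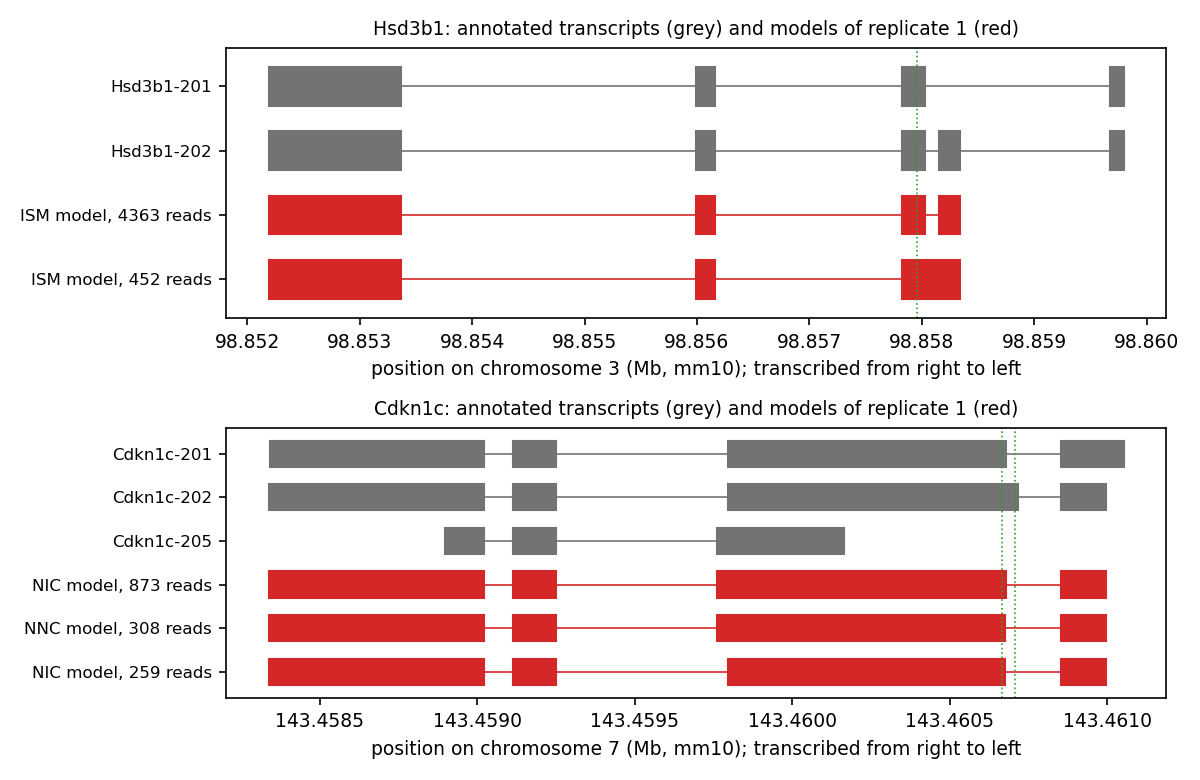
Exon maps (mm10 position on the x axis; boxes are exons, lines introns, green dotted lines annotated start codons) of Hsd3b1 and Cdkn1c, both transcribed from right to left. Annotated transcripts are drawn with the most abundant models not annotated. The Hsd3b1 model with 4363 reads in replicate 1 begins inside the annotated gene.

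Across genes, the leading isoform was mostly the same in both libraries. Of 2440 genes with at least 50 such reads in each library, 2381 (97.6%, 95% Wilson interval 96.9 to 98.1) had the same leading model. The leading model was annotated in 2380 genes and new in 60. Its median share was 92.3% and 91.0%, and 1222 genes had at least 90% in both. There were 130 genes under 50% in both libraries, and 618 with at least 2 models of 10% or more. The shares of the leading models correlated across genes with an r of 0.951. Among abundant genes with no dominant model, the leading known model took 54.0% and 51.6% in Sparc, 41.6% and 34.7% in the RNA-binding gene Cnbp, 55.1% and 52.9% in Mtch1, 56.5% and 57.4% in the lipid synthesis gene Acly, and 49.9% and 48.3% in Fkbp8. It took 49.0% and 59.2% in Eif4h, 56.3% and 59.1% in Hadhb, 39.5% and 50.9% in the myosin gene Myl6, where it did not lead in both libraries, and 56.1% and 58.5% in Aplp2.

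Few genes differed in isoform usage. In the zinc finger gene Zfp771 the share of Zfp771-201 was 75.8% and 38.1% (exact adjusted p 0.0135), and in replicate 2 a new model with 25 reads led. The share of the leading model was in Acsl5 92.1% and 64.9% (exact adjusted p 0.0485), and in the ubiquitin ligase gene Rnf181 74.7% and 51.3% (exact adjusted p 0.00178). Entpd4 had 79.3% and 52.6%, the pyruvate carboxylase gene Pcx 91.9% and 72.8%, the endosomal sorting gene Tsg101 92.4% and 75.3%, Morf4l2 90.5% and 73.6%, the splicing gene Puf60 62.9% and 48.3%, and 2410002F23Rik 42.2% and 70.9%. The tRNA synthetase gene Aars had 57.6% and 87.7%, but a 21-exon model of it was named a new combination in replicate 1 (45 reads) and an incomplete match in replicate 2 (46 reads), with ends 3 bp apart. Of all its reads, Aars-201 held 48.0% and 40.0%. In all, 10 of 2440 genes passed the two-sided Fisher's exact test and the 10-point minimum, 14 passed on the adjusted p alone and 177 had a raw p under 0.05. With known models alone, 1 gene passed, Morf4l2, and with a minimum of 20 reads Acsl5, Pcx and Puf60 did not. The test compares the 2 libraries, not the animals.

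New isoforms shared by both libraries were led by the polyamine regulator gene Oaz1. Its new combination had 1845 ± 122 CPM and took 95.0% and 93.1% of the gene's reads. It differs from Oaz1-201 by lacking a 4-bp gap (80828292 to 80828295 on chromosome 10) that the annotation draws inside an exon, and Oaz2 (346 ± 75.8 CPM) lacks a like gap at 65686269 to 65686272 on chromosome 9. Cdkn1c gave 4 of the 15 most abundant. The first, with 1174 ± 133 CPM and 30.8% and 31.8% of its isoform reads, joins the intron of Cdkn1c-201 at 143460679 to 143460852 to the other introns of Cdkn1c-205. The others had 418 ± 41.6, 332 ± 62.8 and 184 ± 12.8 CPM, and 2 of them share an intron at 143460676 to 143460852 that is not annotated. The mitochondrial ribosome gene Mrpl33 (328 ± 34.7 CPM) had an intron of 2350 bp not in the annotation, at 31614031 to 31616380, and the chaperonin gene Cct6a (176 ± 37.2 CPM) one of 50376 bp at 129794561 to 129844936. Hnrnpk (210.4 ± 16.7 CPM) and Idh3g (165 ± 9.26 CPM) each had 1 intron not annotated, at 58393775 to 58394059 and 73782104 to 73782670. Each takes the place of 2 annotated introns and spans the short exon between them. In Hnrnpk-224 these introns are 58393775 to 58393852 and 58393869 to 58394075. In Idh3g-201 they are 73782104 to 73782297 and 73782310 to 73782674. The prohibitin gene Phb2 (354 ± 6.90 CPM) skipped an exon of 6 bp. Whether such short exons were missed when the reads were aligned was not tested. Ptov1 (324 ± 53.4 CPM), the repressor gene Ctbp1 (306 ± 24.0 CPM), Cyb561 (244 ± 55.5 CPM) and Csnk1g2 (168 ± 27.0 CPM) joined annotated introns in new combinations. The new model of Cyb561 led its gene, with 57.2% and 52.2%.

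In all, replicate 1 held 30011 new multi-exon isoforms and replicate 2 held 34981, and 8298 intron chains were in both. That is 27.6% (95% Wilson interval 27.1 to 28.2) of replicate 1 and 23.7% (23.3 to 24.2) of replicate 2. The share found again grew with reads. Of models with 1 read 17.6% and 14.3% were found again, of those with 2 to 4 reads 60.2% and 54.5%, of those with 5 to 9 reads 92.1% and 88.5%, and of those with at least 10 reads 96.8% and 94.9%. At least 5 reads in each library were held by 836 isoforms of 639 genes. Models seen once made up 62.7% and 62.8% of all models.

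Multi-exon models of new loci, intergenic or antisense to known genes, were few, and the strand of the leading antisense ones is open. The 5 most abundant found in both libraries had 235 ± 9.67 CPM (chromosome 18, 68406907 to 68429320), 38.9 ± 4.50 CPM (chromosome 16, 4128444 to 4213997), 35.9 ± 13.8 CPM (chromosome 5, 148511894 to 148552157), 31.0 ± 5.46 CPM (chromosome 7, 70353993 to 70360593) and 28.6 ± 1.41 CPM (chromosome Y, 43918755 to 43923547). The first 4 lie antisense to Mc2r, the coactivator gene Crebbp, Ubl3 and the stromal transcription factor gene Nr2f2, and every intron of each has the exact ends of an annotated intron of that gene. The locus on chromosome Y, intergenic, lies 28615 bp from the nearest gene, Gm21241. Over all antisense multi-exon models, 40.4% and 43.2% of the reads had introns that all mirror annotated ones. Of 1075 and 1268 multi-exon new locus models, 273 were in both libraries (25.4% and 21.5%).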

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

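Chosen after the results were seen were the tests of liver tissue, carry-over and kidney, of dilution and cortex share, and of naming and genomic DNA, while the tests of transcript length, GC content and liver fragments were set before their results.

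Single-exon reads on the minus strand at chromosome 17, 39843013 to 39846245, reached a mean of 3891 CPM, with 2473 reads (3592 CPM) in replicate 1 and 3397 reads (4190 CPM) in replicate 2. They lie antisense to the lincRNA gene Gm26917, which had 39 and 49 reads of its own, at a locus of ribosomal RNA. The signal lies outside the genes compared, and far above the 4.36 and 3.70 CPM that 3 reads make. It held 12.7% and 10.1% of the single-exon antisense reads of the libraries. No biological explanation was tested.

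Liver genes differed most between the libraries among the fixed lists. Of 26 tested genes in a list of 30 hepatocyte genes, 25 were called higher in replicate 2 (96.2%), with a median log2 ratio of 5.73 and sums of 949 and 27571 CPM. The most abundant in replicate 2 were Trf with 5806 CPM, Ahsg with 3778 CPM and Alb with 3680 CPM; 2 of the list, Apoc1 and Trf, exceeded 100 CPM in replicate 1, and 6 are also in the fixed liver list. Liver tissue taken with the gland of replicate 2 may account for this, but reads carried over from a liver library would raise the summed level alike (log2 ratio 4.86) and cannot be told apart from it, since no value separates them. The kidney list was lower in replicate 2 (ratio 0.359, interval 0.160 to 0.752, 26 and 11 reads, two-sided Fisher's exact p 0.00436). That fall came from Slc34a1 and Aqp2, while the reads of the other members together rose. The list therefore cannot decide whether kidney tissue was taken along.

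Steroid synthesis genes were lower in replicate 2. Dilution of the whole gland by RNA of other tissue cannot be told apart from other causes: the steroid median lay below the chromaffin median by more than random pairs of lists (difference −0.39, percentile 0.71, central 95% of random pairs −0.30 to 0.33), but with known models alone the difference kept its direction, shrank to −0.29 and fell inside a wider interval (−0.34 to 0.40, percentile 4.44), and summed levels had ratios of 0.682 and 0.770. A smaller share of cortex stays open. The capsule list lay above the chromaffin list (difference 0.44, percentile 99.0, central 95% −0.38 to 0.37). With known models alone the difference was still 0.43, but the interval of random pairs widened past it (−0.43 to 0.45, percentile 97.1). The capsule list cannot decide, since the fat and muscle lists were also above random lists and its stromal genes need not come from the gland. The endothelial and macrophage lists differed from the chromaffin list by 0.12 and −0.03, within random pairs (percentiles 73.0 and 49.0). Matching the random lists on transcript length and expression left the steroid median at percentile 0, and matching on GC content and expression also at percentile 0, which argues against both. A difference between the animals or in the parts of the gland sampled stays open and was not tested, and with 1 group no biological explanation was tested.

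Single-exon reads outside known models were more common in replicate 2: genomic and single-exon incomplete reads together took 5.98% and 8.36% of mouse reads, a ratio of 1.40, so the naming of fragments is argued against as the whole cause. Without the 92 genes with a log2 ratio of at least 4 (0.5 CPM added) the ratio was 1.37. This argues against fragments of the transcripts of those genes as the whole cause. Genes under that ratio stayed in, such as Apoe with 616 and 3081 genomic reads, so liver fragments of such genes were not tested. Known single-exon reads (ratio 1.00) and multi-exon reads outside known models (1.01) did not show it, while intronic (1.55) and antisense reads (1.46) did. Of the excess on the sense strand, 84.6% overlapped annotated exons, and 56.2% with antisense reads included. This argues against genomic DNA as the whole cause but not as a part. An earlier comparison had not decided. It set the exonic ratio without those 92 genes (1.36) against the intergenic ratio over all reads (1.34). Over all reads the exonic ratio was 1.39. Broken RNA and priming inside transcripts stay open and were not tested, and no biological explanation was tested.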

How the results depend on the processing

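Leaving out genomic and single-exon incomplete models together, the liver genes, and the genes with a log2 ratio of at least 4 (0.5 CPM added) were alternatives chosen after the data were seen. Leaving out 1 library leaves values without a test.

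No called value changed sign. Of called genes, 48.3% were higher in replicate 2 without a size threshold, and the endothelial, cell cycle and imprinted medians, which were not past random lists, were above 0 with TMM. Beyond the values below, 149 alternative values of summary results and 1637 of single genes or isoforms were counted as unchanged. Those checked stayed within their spread, within a set factor or on their side of the threshold. For levels the spread was the SD of the 2 libraries, so a level with a wide SD could hardly move. Apoe, at 5701 ± 4628 CPM, was for that reason counted as unchanged without genomic models. The levels and class shares of each library alone were counted so without a check, and say nothing on stability. Genes with at least 5 reads in each library numbered 9518, against 14100 with at least 1, and were also counted as unchanged. Of single genes and isoforms, 77 values moved by more than their spread, 16 no longer passed the test and 14 passed it anew.

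From known models alone, list levels were 897 CPM for cholesterol synthesis, 951 for endothelium, 447 for macrophages, 1329.6 for fat, 3343 for cell cycle, 7058 for imprinted, 1031 for mitochondrial and 94.0 for Y-linked genes. With genomic models left out the cell cycle list had 2980.2 CPM. The cause was not tested. With known models alone the fasciculata list stood at percentile 3.23 and the capsule list at 97.4, inside the central 95% of random lists. TMM moves all genes alike, so it does not test these percentiles.

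The count of called genes was 71 (59 higher, 12 lower) with a minimum of 100 reads, where 3144 genes were tested, and 656 (317 and 339) without a size threshold. It was 159 (98 higher, 61 lower) without the genes with a log2 ratio of at least 4; the cause of the fewer lower genes was not tested. TMM and DESeq2's size factors gave 47 and 45 lower genes, since they moved the median of all genes up. Mtfmt lost its call with TMM, DESeq2's size factors and no read minimum. Among the named genes and tested list members, 2 lost their call with no read minimum, Mtfmt included. A call was also lost by 1 with known models alone and by 1 without the genes with a log2 ratio of at least 4. Hba-a1, Col1a2 and Kdr passed with TMM. Pearson's r was 0.873 with no read minimum, 0.869 with a pseudocount of 1 and 0.832 with 0.1, and rho was 0.899 with no read minimum.

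With models of at least 2 and at least 5 reads, complete matches took 77.9% and 82.7% of reads, incomplete matches 8.69% and 7.14%, new combinations 3.41% and 2.49%, new splice sites 1.55% and 0.939%, and intergenic models 0.529% and 0.340%; antisense models took 2.06% at 5 reads. These minimums remove models seen once, which are mostly not annotated.

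The leading model was the same in 96.6% of genes with a minimum of 20 reads, 98.6% with 100 reads and 98.2% with known models alone. Its median share was 88.9%, 94.4% and 98.7% under these, and 83.3% with incomplete matches kept. Isoform usage differed in 4 genes with a minimum of 100 reads, 1 with known models alone and 6 with a minimum of 20 points; with a minimum of 20 reads Acsl5, Pcx and Puf60 did not pass. Of new isoforms with at least 2 reads, 67.6% of replicate 1 and 62.4% of replicate 2 were found again, of those with at least 5 reads 93.8% and 90.7%, and with intron ends within 5 bp 33.6% and 28.6%.

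With each library alone, known genes numbered 15535 to 16618. List sums ranged from 33949.7 to 49752 CPM for steroid synthesis, 2555 to 3948 for zona glomerulosa, 4363 to 7532 for fasciculata, 946 to 1149 for cholesterol synthesis, 11890.5 to 15445 for chromaffin, 52.3 to 119.6 for glia, 4998 to 5683 for capsule, 867 to 909 for endothelium, 379 to 394 for macrophages, 3672 to 7489 for red blood cells, 1868 to 2427 for fat, 13.6 to 37.8 for kidney, 270.2 to 9869 for liver and pancreas, 1389 to 2423 for muscle and 0 to 4.93 for gonadal genes. They ranged from 2827 to 2842 for cell cycle, 8699.9 to 9433 for imprinted, 1855 to 3117 for immediate early, 543 to 932 for mitochondrial and 106 to 119 for Y-linked genes. Shares ranged from 70.1% to 74.2% for complete matches, 9.54% to 10.5% for incomplete, 4.67% to 4.69% for new combinations, 3.24% to 3.45% for new splice sites, 4.49% to 6.35% for genomic, 2.96% to 4.25% for antisense and 0.699% to 0.913% for intergenic models.

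Depth limits genes under 20 reads, which were not tested.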

Other observations

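The gene groups and the tests in this part were all chosen after the data were seen.

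Protein synthesis and respiration genes were a large part of the gland's transcripts. The 74 cytosolic ribosomal protein genes summed to 44211 ± 5535 CPM (40297 and 48126 CPM). Their median log2 ratio was 0.26, and 0 of 73 tested members lay under the median of all genes, though 0 were called. The 92 nuclear genes of the respiratory chain summed to 40194 ± 3890 CPM (37443 and 42944 CPM), with a median of 0.25; 9 of 88 tested members lay under the median of all genes and 1 was called.

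The summed levels of collagen and globin genes were higher in replicate 2. The 36 collagen genes summed to 3143 and 4636 CPM (3890 ± 1055), with a median of 0.55 and 1 of 15 tested genes called. The adult globin genes summed to 3627 and 7390 CPM (5509 ± 2661), with 2 called, and no embryonic globin gene had a read.

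Reads that mirror the introns of a gene on its other strand were found beyond Mc2r. The matrix gene Ccdc80 had 25 and 27 such reads, the splicing gene Mbnl1 15 and 28, the growth factor receptor gene Igf1r 13 and 18, Tshz1 15 and 16, and the antigen-presenting gene B2m 10 and 15. Together, antisense multi-exon models with all introns mirrored numbered 148 and 200, with 517 and 693 reads.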
